A study of Mus musculus with 8 samples.

How the data were processed

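RNA from bone marrow derived macrophages (macrophages grown in culture from marrow precursors) of Padi4 knockout and wild-type mice was sequenced, with 4 libraries per genotype. Padi4 encodes PAD4, an enzyme that converts arginine to citrulline in proteins. Per the labels' protocols, total RNA was taken with Trizol and libraries followed a BGISEQ RNA-seq protocol. Groups came from the sample titles. The series' design text calls the samples of each group independent, but no label used here names the animal, culture or day behind a library, so the p-values measure the spread between these libraries, part of which may be technical.

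The values are FPKM (fragments scaled to transcript length and library size) per gene, deposited by the authors to 2 decimals. Per the submitters' processing notes, the authors used HISAT, Bowtie2, RSEM and the GRCm38 build; versions and settings are not given in the sources used here. The same deposited table holds the authors' log2 fold change and q-value per gene, and the test behind them is not given in the sources used here. The deposited FPKM values give no depth: whole reads could not be recovered from values that RSEM estimates, so the depth is unknown and no counting interval is given. The table held here lists 6287 genes, all of the mRNA type, and how they were chosen is not stated. Padi4 and the rest of the PAD family were not analysed here, and the results of some single genes are not reported here.

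The test was limma (version 3.58.1 in R 4.3.3) on log2(FPKM + 1), with a mean-variance trend and robust empirical Bayes, two-sided, and Benjamini-Hochberg adjustment. Genes with a mean FPKM of at least 1 over the 8 libraries were tested, which kept 5674 and left out 613, of which 10 were listed at 0 in every library. A gene was called at an adjusted p below 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, so the ratio of the mean FPKM is given beside them. A reported mean is followed by its SD over 4 libraries. Gene identifiers were matched to a RefSeq table of GRCm38.p6, in which 6271 of the 6287 were found, and coordinates are from that table.

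Before the data were examined, the test, 28 gene lists and the rule for named genes were fixed. The rule took the PAD family, the 12 higher and the 12 lower called genes with the largest log2 fold change among those whose groups did not overlap, leaving out predicted or clone-named genes, and up to 4 members of each list with the smallest adjusted p. Srebf2, Fn1, Mmp14 and Cebpb lie outside this rule and were picked after their values were seen, so their calls were not followed through the alternatives. The lists cover the PAD family and Padi4's neighbours on chromosome 4, chemoattractant receptors, chemokines, integrins and adhesion, the actin cytoskeleton, matrix and proteases, pro-inflammatory and alternative activation, the interferon response, MHC class II, cell cycle, hypoxia and glycolysis, cholesterol synthesis, cholesterol efflux, phagocytosis, immediate early genes, the unfolded protein response, macrophage identity and sex-linked genes. They also cover markers of neutrophils, dendritic cells, osteoclasts, fibroblasts, T and NK cells, B cells, mast cells and erythroid cells. Lists with at least 5 tested members, 16 in all, were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes. Camera with an estimated correlation and fry were the alternatives. Members called are counted over all genes tested and also adjusted over the list alone. A further 4 lists were written after the data were seen and appear only among the other observations.

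Alternatives covered the pseudocount, the filter, library scaling (TPM, median-of-ratios, quantile normalization), empirical Bayes settings, library weights, a replicate block, and leaving out each library. Others were added after the data were seen: leaving out knockout replicates 3 and 4, removing the trend with transcript length, and combinations with median-of-ratios scaling. Knockout replicates 3 and 4 alone against wild type were also compared once after the data were seen. That comparison called more genes in each direction, and it was removed because it keeps the libraries that lay farthest from wild type; replicates 1 and 2 alone were likewise picked after the data were seen. Tests that need read counts were not run. A result that was not called and changed sign without being called was counted as unmoved, a choice made here. For explanations weighed below, a prediction was written for each; 2 verdicts, on scaling and on transcript length as reasons for the excess of higher genes, were left open after their results were seen, because both corrections centre the values and so fix part of the outcome. The prediction written beforehand for length would have spoken against it.

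The procedure was tested on simulated data for this comparison: 5 sets of 5674 genes with 200 changed genes. It recovered 45.4% of changes of 0.25 on the log2 scale, 87.2% of changes of 0.5 and 96.7% of changes of 1, and 3.82% of its calls were false. The simulated noise was independent between libraries, with the same SD per gene in both groups. In the data the SD was larger in the knockout for 73.07% of genes. Deviations from the group mean correlated at 0.545 between knockout replicates 1 and 2 and at 0.624 between replicates 3 and 4. These rates therefore need not hold for this comparison.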

Results

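Gene expression was measured by RNA-seq in cultured macrophages from the bone marrow of 4 wild-type and 4 Padi4 knockout samples. The comparison asks which genes differ between macrophages with and without PAD4, in a series whose title concerns macrophage migration. FPKM summed to between 381573 and 403848 per library over the listed genes, and the number of reads behind these values is unknown. The level of Padi4 was not analysed here, so the genotype labels were not checked by the targeted gene.

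Among the genes that changed in macrophages without Padi4, several that encode matrix-degrading proteases or cholesterol synthesis enzymes were lower. Neither list's camera call held with an estimated correlation (adjusted p = 0.09999 for both). Each list was called in 23 of 24 alternatives, fry among them (fry adjusted p = 0.000457 for both). Maoa, which encodes a mitochondrial monoamine oxidase, fell from 21.0 ± 0.956 FPKM (SD, n = 4) in wild type to 5.47 ± 0.715 (SD, n = 4) in the knockout, a ratio of 0.260. Mmp12, the macrophage elastase, fell from 1726 ± 20.2 to 788 ± 188 FPKM, and the chemokine receptor gene Ccr1 fell from 54.41 ± 2.90 to 25.97 ± 6.14. Complement component C3 rose from 7.01 ± 0.527 to 23.6 ± 6.58 FPKM, and Ly6e, an interferon-inducible gene of the Ly6 family, rose from 13.4 ± 1.64 to 53.8 ± 29.6. Their adjusted p-values in limma were 1.83e-06 for Maoa, 0.00256 for Mmp12, 0.00291 for Ccr1, 0.00131 for C3 and 0.0148 for Ly6e.

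**Figure D1:**
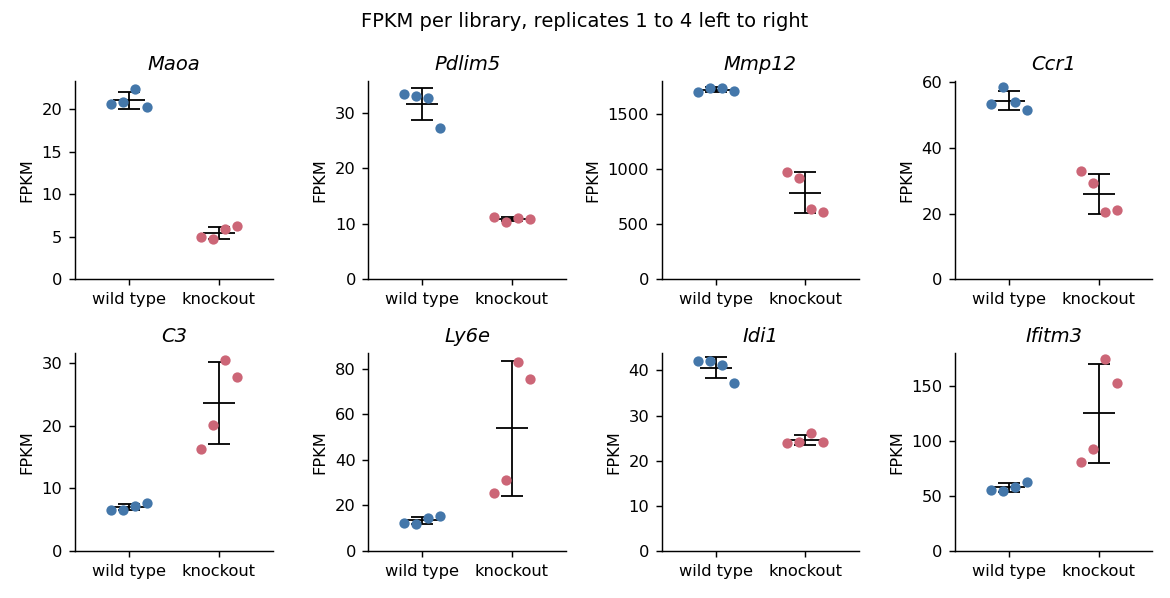
FPKM of 8 genes in each library, with wild type in blue and Padi4 knockout in red; the bar shows the mean and the SD of 4 libraries, and points run from replicate 1 to 4. For Maoa the knockout libraries lie between 4.78 and 6.21 FPKM and the wild-type libraries between 20.26 and 22.41, whereas for Ly6e and Ifitm3 knockout replicates 3 and 4 lie well above knockout replicates 1 and 2.

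Of 5674 genes tested, 1195 were higher and 375 lower in the knockout, which is 27.7% of the genes tested. Most changes were small. The median absolute log2 fold change of called genes was 0.27, and 16 genes were higher and 11 lower by at least 1 on the log2 scale. Groups did not overlap for 31.1% of tested genes, against 2.86% by chance. This share was counted on the deposited scale only, where the median gene lay 0.082 higher in the knockout, so scaling may have raised it. The split between higher and lower depended on scaling. With median-of-ratios scaling, which sets the typical gene to no change, 514 genes were higher and 636 lower, so that 44.7% of called genes were higher instead of 76.1%. The 514 higher genes were among the 1195, the 375 lower genes were among the 636, and none turned direction. This nesting follows largely from a scaling that lowers nearly all fold changes alike, so it is no sign of robustness. Leaving out 1 library moved the number of higher genes by over 1.5 times for wild-type replicates 1, 2 and 3 (661, 647 and 659) and knockout replicates 3 and 4 (681 and 729), and the number of lower genes for wild-type replicates 2 and 3 (237 and 243). The 27 genes changed by at least 1 became 43 and 41 without knockout replicates 1 and 2, 14 and 13 without replicates 3 and 4, and 7 without both replicates 3 and 4.

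The libraries of the knockout group were not alike. On the first principal component, which held 70.6% of the variance, the wild-type libraries lay between -9.02 and -8.15, knockout replicates 1 and 2 at -0.91 and 1.42, and knockout replicates 3 and 4 at 17.7 and 16.1. The median SD over genes was 0.099 on the log2 scale in the knockout and 0.066 in wild type. With knockout replicates 3 and 4 left out, 666 genes were higher and 291 lower, and 809 of these 957 were also called with all libraries, in the same direction.

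**Figure D2:**
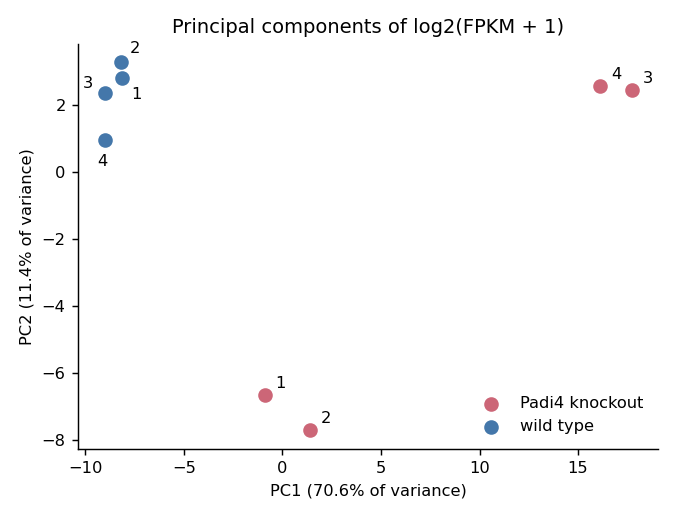
The first and second principal components of log2(FPKM + 1) over the tested genes, with each point a library labelled by its replicate number. The 4 wild-type libraries lie together, and the knockout libraries lie in 2 pairs, replicates 1 and 2 and replicates 3 and 4, along a first component with 70.6% of the variance.

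The genes with the largest decreases included several with little spread. Pdlim5 (chromosome 3, 142239585 to 142395719), which encodes a PDZ and LIM domain protein of the actin cytoskeleton, fell from 31.6 ± 2.91 to 10.8 ± 0.422 FPKM (log2 fold change -1.45, SE 0.067, adjusted p = 1.83e-06). Maoa (chromosome X, 16619698 to 16687812) had a log2 fold change of -1.77 (SE 0.077). Mamdc2 fell to a ratio of 0.272 and Cd200, a ligand that restrains myeloid cells, to 0.417. Fabp4, a fatty acid binding protein, fell from 369 ± 16.3 to 163 ± 60.9 FPKM. Cdkn1c, an inhibitor of cyclin-dependent kinases, fell to a ratio of 0.397, and the cathepsin genes Ctsk and Ctsl to 0.448 and 0.502. Slamf8 and Tm4sf19 complete the 12 decreases, at ratios of 0.454 and 0.456. These decreases, together with those of Mmp12 and Ccr1, kept their call in each alternative run.

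Many of the largest increases after Ly6e and C3 varied widely between knockout libraries, but those of Dmpk and Ctla2a less so. Zfp36l1, which encodes an RNA-binding protein that promotes mRNA decay, rose from 0.54 ± 0.058 to 2.59 ± 1.41 FPKM. Marcksl1, an actin regulator, rose to a ratio of 2.76. Gpr84, a receptor for medium-chain fatty acids, rose to 2.33, and the kinase gene Dmpk to 2.55 with values of 10.8 to 15.14 FPKM in the 4 knockout libraries. Ctla2a rose from 21.4 ± 1.99 to 51.1 ± 7.81 FPKM. It has a close paralog, and the settings with which RSEM divided shared reads are not given in the sources used here. Slc2a6, a glucose transporter gene, Icosl, Cd69 and Calhm6 had ratios of 4.67, 2.64, 2.69 and 3.05. The calls of Slc2a6, Cd69 and Calhm6 were lost without any 1 of wild-type replicates 1 to 4 or knockout replicates 3 and 4, and that of Icosl without wild-type replicates 1 or 3 or knockout replicate 4, with adjusted p-values over all alternatives of up to 0.103, 0.109, 0.0889 and 0.0711. The call of Slc2a6 was also lost with median-of-ratios scaling. A further 22 higher and 3 lower called genes had predicted or clone names.

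**Figure D3:**
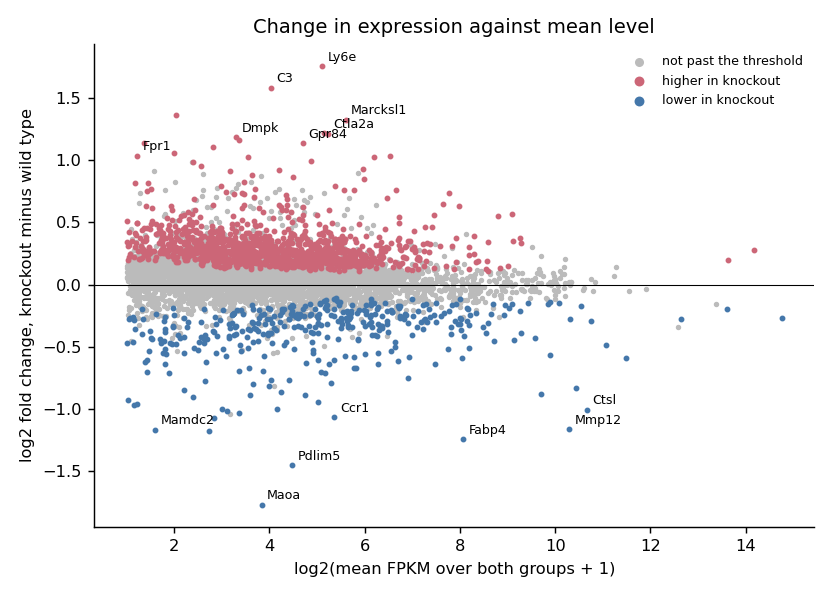
Log2 fold change, knockout minus wild type, against the log2 of the mean FPKM plus 1, with each point a tested gene, red where higher and blue where lower at an adjusted p below 0.05. The 1195 higher genes mostly lie at small positive values, and the largest changes are those of Ly6e (1.76) and Maoa (-1.77).

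Most tested genes of cholesterol synthesis were lower. Of 13 tested members, 9 fell and none rose; adjusted over the list alone, 11 fell. Idi1, an isomerase of the isoprenoid pathway, fell from 40.7 ± 2.31 to 24.6 ± 1.07 FPKM. Sqle, which encodes squalene epoxidase, fell from 31.9 ± 1.78 to 20.2 ± 0.602, Msmo1 from 116 ± 6.03 to 81.2 ± 3.69, and Insig1, a sterol-regulated anchor protein, from 66.0 ± 3.74 to 48.3 ± 1.99. Srebf2, which encodes the transcription factor of the pathway, had a ratio of 1.06 (adjusted p = 0.230). The list fell relative to other genes by camera with adjusted p = 6.66e-12, but with adjusted p = 0.09999 with an estimated correlation; over all alternatives the adjusted p ran from 2.60e-14 to 0.09999. Median differences from the wild-type mean were -0.36, -0.40, -0.18 and -0.37 in knockout replicates 1 to 4. Of 5 tested genes of cholesterol efflux and LXR targets, Abca1 rose to a ratio of 1.57 and Scd2 fell to 0.551, the same adjusted over the list alone. With median-of-ratios scaling 1 rose and 3 fell, as Apoe and Abcg1 also passed there (log2 fold change -0.24 and -0.16, adjusted p = 0.0233 and 0.0339).

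Most tested matrix proteins and proteases were lower. Of 10 tested members, 8 fell, 1 rose and 1 did not pass the test, with the same counts adjusted over the list alone. The metalloproteinase gene Mmp13 fell to a ratio of 0.571, and Adam19 fell from 1.97 ± 0.125 to 0.52 ± 0.107 FPKM. The cathepsin gene Ctss fell from 2487 ± 100.2 to 1775 ± 136.5 FPKM. Fn1, which encodes fibronectin, was the member that rose, to a ratio of 1.30, and Mmp14 had a ratio of 1.29 (adjusted p = 0.506). Camera gave adjusted p = 4.68e-09, and adjusted p = 0.09999 with an estimated correlation, with a range over all alternatives of 3.52e-12 to 0.09999. These were the only fixed lists that camera called, 2 of 16, and neither call held with an estimated correlation. The list's median lay at -0.55 and -0.59 in knockout replicates 1 and 2 and at -0.98 and -0.92 in replicates 3 and 4.

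Of 18 tested genes of pro-inflammatory activation, 10 rose and 1 fell; adjusted over the list alone, 11 rose and 2 fell. With median-of-ratios scaling 7 rose and 2 fell. Tlr2, a receptor for bacterial lipoproteins, rose from 140.2 ± 1.64 to 209 ± 31.2 FPKM, and Ptgs2, which encodes cyclooxygenase 2, rose to a ratio of 1.53. Tlr4, the receptor for lipopolysaccharide, rose to 1.22. Il1rn, the antagonist of the interleukin 1 receptor, fell from 41.7 ± 2.07 to 21.5 ± 5.09. As a list, the group did not pass camera (adjusted p = 0.0921, and adjusted p = 0.593 with an estimated correlation), but passed without knockout replicate 2 (adjusted p = 0.0291) and with median-of-ratios scaling; over all alternatives the adjusted p ran from 0.00312 to 0.593. Its median lay at 0.15 and 0.17 in knockout replicates 1 and 2 and at 0.43 and 0.50 in replicates 3 and 4.

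All 26 tested interferon-response genes had a higher mean in the knockout, but 2 passed the test, with the same count adjusted over the list alone. Bst2, which tethers virus particles, rose from 162 ± 5.08 to 275 ± 58.4 FPKM and Ifitm3 from 57.8 ± 3.92 to 125 ± 45.4. The call of Ifitm3 was lost without wild-type replicate 1 or 2 (adjusted p = 0.0508 and 0.0509), and Ifitm3 belongs to a family of near-identical genes. Ifi44 and Isg20 had ratios of 2.92 and 1.59 (adjusted p = 0.0955 and 0.101), and both passed without knockout replicate 1 (0.0300 and 0.0113). The list's median difference from the wild-type mean was 0.0059 and 0.021 in knockout replicates 1 and 2 but 1.37 and 1.09 in replicates 3 and 4, and between -0.19 and 0.17 in wild type. Camera gave adjusted p = 0.0921, and adjusted p = 0.762 with an estimated correlation. The list passed without knockout replicate 1 or 2 (adjusted p = 0.0116 and 0.00398) and with median-of-ratios scaling; over all alternatives the adjusted p ran from 5.15e-07 to 0.762.

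**Figure D4:**
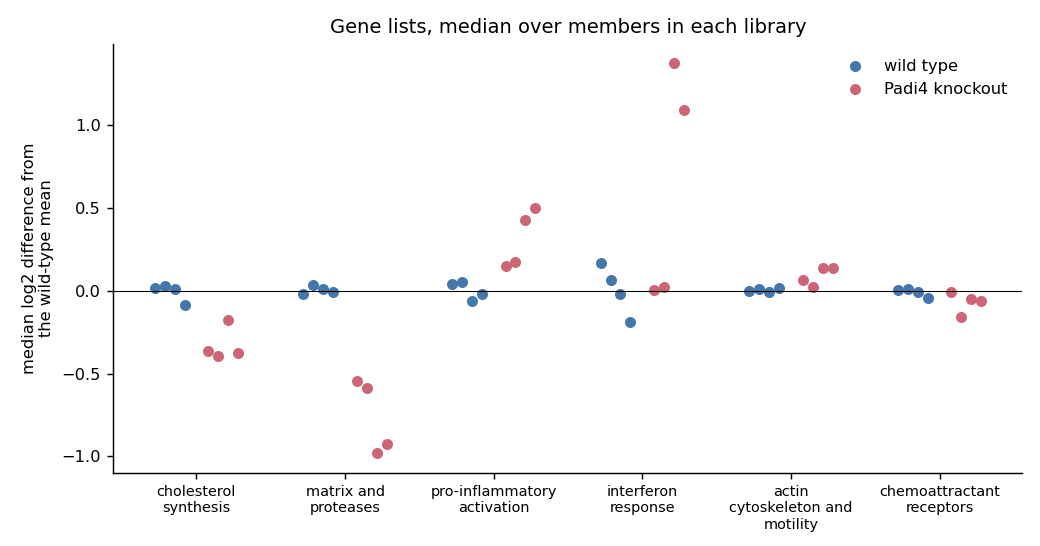
Median over the members of 6 gene lists of the log2 difference from the wild-type mean, for each library, with wild type in blue and knockout in red and replicates 1 to 4 from left to right. Cholesterol synthesis lies below 0 in all 4 knockout libraries, whereas the interferon median exceeds 1 in knockout replicates 3 and 4 and is close to 0 in replicates 1 and 2.

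Genes linked to migration moved in both directions. Among 12 chemoattractant receptors, 4 rose and 3 fell (4 and 6 adjusted over the list alone). Fpr1 and Fpr2, neighbouring formyl peptide receptor genes of similar sequence, rose from 0.51 ± 0.189 to 2.16 ± 0.799 and from 0.94 ± 0.110 to 2.49 ± 0.857 FPKM, and Csf1r rose from 536 ± 12.4 to 696 ± 54.0. Of 14 chemokines, 4 rose and 1 fell, the same adjusted over the list alone. Ccl4 had a ratio of 1.30, and Ccl5 one of 1.87, a call lost without wild-type replicate 3 (adjusted p = 0.0519). Ccl6 fell to 0.876. Of 14 integrin and adhesion genes, 3 rose and 3 fell (5 and 3 adjusted over the list alone): Itgal rose to a ratio of 2.09, whereas Itgax and Cd44 fell to 0.681 and 0.668. Itgam rose to 1.16, a call lost with median-of-ratios scaling. With median-of-ratios scaling, 3 chemoattractant receptors rose and 4 fell, 2 chemokines rose and 1 fell, and 2 integrin and adhesion genes rose and 4 fell. Of 25 actin and motility genes, 9 rose and 3 fell (11 and 3 adjusted over the list alone), and 3 rose and 3 fell with median-of-ratios scaling. Vim, which encodes vimentin, fell from 1067 ± 41.7 to 592 ± 149 FPKM, Vav3 fell to a ratio of 0.762, and Marcks rose to 1.25. Camera called none of these lists (adjusted p = 0.0921, 0.623, 0.252 and 0.928), but chemoattractant receptors passed downwards with a filter at a mean FPKM of 5 (adjusted p = 0.00976, with a range over all alternatives of 0.00976 to 0.360). The medians of the chemokines and of the integrins were positive (0.057 and 0.010) while camera pointed down, since the median of all genes was 0.082, and both medians were negative with median-of-ratios scaling (-0.023 and -0.078).

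Of 11 tested markers of macrophage identity, 7 rose and 1 fell (8 and 1 adjusted over the list alone), and 3 rose and 1 fell with median-of-ratios scaling. Cd14, a co-receptor for lipopolysaccharide, rose from 127 ± 2.54 to 178 ± 31.9 FPKM, and Cebpb fell to a ratio of 0.839. The list did not pass camera (adjusted p = 0.132, and adjusted p = 0.593 with an estimated correlation), but passed with quantile normalization and with fry, with a range over all alternatives of 0.0104 to 0.593. Its median lay at 0.12 and 0.16 in knockout replicates 1 and 2 and at 0.39 and 0.28 in replicates 3 and 4. Of 4 osteoclast markers, Ctsk and Acp5 fell and the other 2 did not pass; adjusted over the list alone, 2 rose and 2 fell. Irf8, the only dendritic cell marker tested, had a ratio of 1.12 (adjusted p = 0.0981), and passed alone in its list and without knockout replicate 1. Lcn2, from the neutrophil list, and Col3a1 and Pdgfra, from the fibroblast list, were below the minimum. Markers of T and NK cells, B cells, mast cells and erythroid cells were not analysed here. The Y-linked genes Kdm5d, Uty and Eif2s3y were detected in all 8 libraries, and none of the 3 passed the test, although Kdm5d and Uty were higher adjusted over the list alone and Kdm5d also without knockout replicate 4.

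Of 10 unfolded protein and heat shock genes, 5 rose and 1 fell, the same adjusted over the list alone, with Hspa5 at a ratio of 1.29 and Pdia4 at 1.41; 3 rose and 1 fell with median-of-ratios scaling. In the cell cycle list of 12, Mki67 rose to 1.32 and Ccne2 and Pcna fell to 0.569 and 0.740, the last call being lost without wild-type replicate 3 (adjusted p = 0.0527). Of 13 genes of hypoxia and glycolysis 3 rose and 2 fell, including Slc16a3 (1.34) and Pgam1 (0.846). Of 10 genes of phagocytosis and scavenging 2 rose and 3 fell, with Axl at 1.32, Gas6 at 1.24 and the scavenger receptor gene Cd36 at 0.578, and of 10 immediate early genes 3 rose and 2 fell, with Dusp1 at 0.724. Of 4 alternative activation genes, Folr2 fell (0.786) and the others did not pass, but Mrc1 and Il4ra did without knockout replicate 2 (adjusted p = 0.0356 and 0.0138) and Tgfb1 without knockout replicate 1 (0.0357). Of 11 neighbours of Padi4 on chromosome 4, Ubr4 and Rcc2 rose to 1.27 and 1.25. Ciita, the only MHC class II gene listed, was below the minimum. None of the 6 lists among these with at least 5 tested members passed camera. The lowest adjusted p was 0.0635 for the cell cycle, with adjusted p = 0.503 with an estimated correlation. The cell cycle list passed without wild-type replicate 3 or 4 (adjusted p = 0.0251 and 0.0455) or knockout replicate 1 or 2 (0.0210 and 0.0291). For hypoxia and immediate early genes the medians were positive (0.037 and 0.050) while camera pointed down. Fry called 3 of these lists upwards: the neighbours (adjusted p = 0.00848), unfolded protein and heat shock (0.0149) and hypoxia (0.0439). It does not compare a list with other genes, whose median was itself 0.082. Adjusted over the list alone, the counts higher and lower were 1 and 2 for the cell cycle, 3 and 2 for hypoxia, 4 and 3 for phagocytosis, 4 and 3 for immediate early genes and 2 and 0 for the neighbours, and 0 and 1 for alternative activation.

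In the authors' deposited table, 582 genes were higher and 616 lower at a q-value below 0.05, so that 48.6% of their calls were higher. Of the 1160 of these among the genes tested here, 906 were also called here, all in the same direction, and 254 were not; 664 genes were called here only. With median-of-ratios scaling 1009 of the authors' calls were also called here in the same direction, and 44.7% of the calls here were higher. The median log2 fold change in the authors' deposited table was 0.012 over the genes tested here. The log2 fold change of Maoa was -2.03 and that of C3 was 1.65 in the authors' deposited table.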

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

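No test in this part was chosen after its result was seen. A single library far from the other 3 of its group was found in 11 of 190 groups of 4 values checked, where chance alone gives about 9.5. In wild-type replicate 4, Pdlim5 (27.22 FPKM), Fabp4 (344.28), Msmo1 (106.76), Insig1 (60.39) and Acp5 (5.91) lay below the other wild-type libraries. In wild-type replicate 1, Dmpk (5.56) and Itgam (134.44) lay above the others. In knockout replicate 2, Ctla2a (39.5) lay below and Mrto4 (19.3) and Il4ra (35.69) lay above the other knockout libraries. Idi1 (26.21) lay above the others in knockout replicate 3. No explanation was tested for these values.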

How the results depend on the processing

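The alternatives leaving out knockout replicates 3 and 4, removing the length trend and joining 2 choices were chosen after the data were seen. Counts below are given against 1195 genes higher, 375 lower, 27 changed by at least 1 on the log2 scale and 2 gene lists past camera. The cause of a shift was not tested unless stated. No called gene that the fixed rule named turned direction in any alternative run.

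Median-of-ratios scaling gave 514 higher and 636 lower, since it moves the median gene from 0.082 to 0.0033. It gave 4 lists, for which the cause was not tested; with the length trend also removed it gave 486, 644 and 4, and with library weights 1331 lower, 58 changed by at least 1 and 5 lists. Quantile normalization gave 488 higher and 6 lists. Library weights alone gave 2229 higher, 746 lower, 71 changed by at least 1 and 4 lists. The weights were 0.280 and 0.385 for knockout replicates 1 and 2 but 1.13 and 1.51 for replicates 3 and 4. Within the knockout they thus favour the libraries farthest from wild type. The TPM scale gave 41 and a pseudocount of 0.1 gave 45 genes changed by at least 1. A filter at a mean FPKM of 5 gave 4 lists. Knockout replicates 1 and 2 alone against wild type gave 666 higher and 7 changed by at least 1. Camera with an estimated correlation called 0 of 16 lists, and fry, which tests whether a list's own genes move one way, called 8. Hypoxia and glycolysis pointed down in camera and up in fry, with a median of 0.037 (fry adjusted p = 0.0439).

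Leaving out each library in turn gave 647 to 1682 genes higher, 237 to 544 lower, 13 to 43 changed by at least 1 and 2 to 5 lists. The highest counts came without knockout replicate 1 (1682, 544 and 43). Genes changed by at least 1 were 41 without knockout replicate 2, 14 without replicate 3 and 13 without replicate 4, and lists were 4 and 5 without knockout replicates 1 and 2.

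The groups share replicate numbers, and the values showed no sign that these pair the samples. Deviations of same-numbered libraries from their group means correlated across genes at -0.032, -0.14, -0.060 and -0.060. No library correlated best with its own number. Such correlations cannot exclude a shared preparation, and no label used here gives animal, culture or day. With the replicate block 1365 genes were called, 1268 of them also called without it; the block gave 1031 higher and 334 lower. It ended the calls of Slc2a6, Icosl, Cd69, Calhm6, Ccl5, Cxcl16, Ldha and Jun, and Irf8, Kdm5d and the cell cycle list passed with it. Tests on read counts were not run, since no counts were used here, and neither was the planned test of the Padi4 level. The unknown depth limits what can be said of genes with low values.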

Other observations

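The 4 gene groups described first, and the tests of scaling as a reason for the excess of higher genes and for the interferon spread, of the culture, of the Padi4 segment and of the decreases with the smallest p, were chosen after the results were seen. Lysosomal proteins moved in both directions: of 16 tested, 7 fell and 3 rose. The protease genes Lgmn and Ctsh fell to ratios of 0.765 and 0.760, and Npc2, a cholesterol carrier of the lysosome, to 0.849, whereas Scarb2 and Ctsc rose to 1.22 and 1.30. Camera gave p = 0.000210 for a fall relative to other genes, with adjusted p = 0.0302 with an estimated correlation. Of 11 genes of lipid uptake and PPAR-gamma targets, 6 fell and none rose, among them Pparg from 34.1 ± 3.07 to 23.8 ± 5.65 FPKM (SD, n = 4). For this list limma's camera gave p = 7.44e-05 and adjusted p = 0.0394 with an estimated correlation. Both lists share members with lists described above. All 4 groups were chosen with the results in view, so their camera p-values describe these data and are not evidence of a shift. Adjustment was over these 4 lists alone.

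Of 22 chromatin remodelling and histone modification genes, 16 rose and Kdm6b, a histone demethylase, fell to a ratio of 0.639. Ep400 and Kmt2d rose to ratios of 1.30 and 1.29. Camera gave p = 2.14e-05, but adjusted p = 0.148 with an estimated correlation, and 8 rose with median-of-ratios scaling. With the length trend removed the p was 0.000597. A rise of co-stimulatory and activation surface proteins depended on scaling. Of 10 tested, 5 rose, including Cd83 (1.79) and Tnfsf4 (2.11), and 1 fell. Limma's camera gave p = 0.181, with adjusted p = 0.598 with an estimated correlation. With median-of-ratios scaling 4 rose and 1 fell, and limma's camera with the preset correlation across genes gave p = 0.0204.

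Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes changed, higher or lower, the real one, with 1570, 1195 and 375 against at most 0 in any other split. Every other split mixes the genotypes, so a genotype difference would itself widen the spread within its groups. For the number of lists 22 of 35 splits gave at least 2, and the highest of the others was 5, so these splits do not exclude chance. They do not exclude it for the camera p of cholesterol synthesis either, since 3 of 35 gave one as small as 4.16e-13 (smallest other 4.93e-15). Both other splits, however, set 3 wild-type libraries and knockout replicate 3 against the rest and so keep much of the genotype difference, and among splits with 2 libraries of each genotype on each side the smallest p was 0.0302. For matrix and proteases 1 split gave a p as small as 5.86e-10, the real one, with 1.44e-05 the smallest other.

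More genes were higher than lower in the knockout, with a median of all genes at 0.082. The 50 most abundant genes held 40.7% of FPKM in wild type and 38.7% in the knockout. Without them and with library totals set equal, the median was 0.061, against 0.108 on the TPM scale, where totals are also equal. These genes may thus account for part of the excess, but the remaining 0.061 argues against them as the whole cause. Scaling by the authors stays open: 44.7% of called genes were higher after median-of-ratios scaling, near the 48.6% of the authors' deposited calls, but that scaling centres the median gene and would do so for a real rise as well. A length trend stays open as a part of the cause. The fold change correlated with transcript length across genes at 0.121 (Spearman). Its correlations with GC content (0.157) and with mean expression (-0.177) were larger in size, and neither was tested as a cause. Of the 1402 shortest genes 178 were higher and 120 lower, against 402 and 62 of the 1400 longest. Removing the trend left 1197 higher, but that correction is centred and cannot shift all genes together. Deviations from the mean correlated with length at 0.207 and 0.318 in knockout replicates 1 and 2 but 0.034 and -0.136 in replicates 3 and 4. Median-of-ratios size factors were larger in replicates 3 and 4 (1.057 and 1.043) than in replicates 1 and 2 (1.011 and 1.02). This argues against length as the whole cause in replicates 3 and 4. A broad rise in the knockout itself may also contribute and cannot be told apart from scaling, as no spike-in or read total was used here.

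Interferon genes differed between knockout libraries, with a range of 1.367 on the log2 scale between their list medians, against 0.361 in wild type. The range was 1.345 after removing the length trend and 1.295 after median-of-ratios scaling, which argues against both as the cause. A difference between the knockout cultures, animals or days may be the source, but no label used here gives these, so the range of 1.367 decides nothing and a variable effect of the genotype stays open.

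Large decreases with little spread, such as those of Maoa, Pdlim5 and Mamdc2, could come from strain variants carried along with the knockout. None of these decreases lay within 10 Mb of Padi4, so a segment around that locus would not contain them. Of 92 genes there, 1.09% were changed by at least 0.5 against 3.05% elsewhere (Fisher's exact test, two-sided, p = 0.530). The confidence interval of the odds ratio ran from 0.0087 to 2.02, so this share cannot exclude such a segment. Changed genes did follow each other along the genome more often than in shuffles, with 9 pairs against a mean of 2.57 (percentile 99.91). Blocks elsewhere would give this. The pairs include the families Mmp13, Mmp12 and Mmp10 and Fpr1 with Fpr2, which may share regulation. They also include Klf9 with Mamdc2 on chromosome 19, both lower and with starts 161.4 kb apart. Around the decreases taken as a set, genes called lower were not in excess, while neighbours called higher were not counted. The confidence intervals of the odds ratios below were wide, at 0.394 to 1.75 and 0.114 to 1.73. Within 2 Mb of 11 evenly decreased genes 5.73% of genes were lower against 6.43% elsewhere (Fisher's exact test, p = 0.869). Around the 11 decreases with the smallest p, which include Maoa and Pdlim5, 3.75% were lower against 6.44% (Fisher's exact test, p = 0.487). Variants in single genes, blocks around single decreases such as Mamdc2 and an effect of the genotype stay open.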
